A study of Betula luminifera with 4 samples.

How the data were processed

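Small RNA libraries were made from Betula luminifera plants of clone G49, 1 library for roots and 1 for shoots under each of 2 treatments, and sequenced as 36-nt single reads on an Illumina HiSeq instrument, per the labels' protocols. Per the same protocols, 54 plants raised in tissue culture and moved to sand were divided between the treatments in a block design with 3 replicates, root RNA gave the root library, and equal amounts of stem and leaf RNA were pooled for the shoot library. About 1 µg of total RNA with an RNA integrity number above 7.0 entered a TruSeq small RNA kit, per the labels' protocols. The labels do not tie the 3 blocks to libraries, so each group is 1 library and the number of plants behind it is not given in the sources used here.

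The series has 1 table of 221 rows, each a mature miRNA with its name, arm, length and sequence and, for 147 rows, a precursor position on a transcript of the authors' assembly. The raw columns are estimated counts of reads as deposited by the authors, who named them raw in the header. Most are whole, and 84 distinct sequences have fractional values in at least 1 library, as reads split between several places would give. The normalized columns, named norm per the file headers, hold a signal that the authors made by multiplying each raw column by 1 constant, 1.02 for root CK, 2.73 for root LP, 0.517 for shoot CK and 0.780 for shoot LP, as the ratio of both columns shows in every row. How these constants were chosen, the aligner, the counting program, the filters and the miRBase release are not given in the sources used here. The authors sorted the rows into 3 expression levels, and the 49 rows at their low level have no normalized value of 10 or more in any library. A further 2 lines of the table were blank and were not analysed here. No column of values was left without a sample.

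Rows with the same mature sequence were collapsed, which left 215 distinct sequences, since the repeated rows hold the same values. If the deposited value of such a row is its share of the reads, collapsing understates miR156, miR172 and miR393, and the analysis of all rows as deposited was therefore run beside it. A family is all distinct sequences with the same number after miR, summed, and 56 families have such a name. Totals of the raw columns, 104172 to 1022673 reads over all rows and 101816 to 1015833 over the distinct sequences, are totals of this table, not of the whole libraries, whose depth was not used here. The table seldom lists exactly 1 read, 5 of 705 values above 0, so a value of 0 can hide a read, and no upper limit is given for values of 0.

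The comparisons are LP against CK in roots, LP against CK in shoots, and root against shoot under CK and under LP. With 1 library per group there is no test and no p-value. Ratios are given on the log2(value + 1) scale of the normalized values, which understates the change of low values, and folds as plain ratios of the normalized values. Each fold has an exact conditional interval (Clopper-Pearson, 95%) from the raw reads rounded to whole numbers and scaled by the authors' constants, and each share of reads an exact binomial interval. Reads amplified by PCR are not independent molecules, so these intervals cover counting error only, and they compare libraries, not conditions. A sequence counts as higher or lower at 2-fold or more with a normalized value of at least 10 in 1 of the libraries compared.

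These choices, the alternatives, 7 family lists and the naming rule were fixed before the data were examined. The lists were phosphate starvation (miR399, miR827, miR2111, miR778), copper responsive (miR397, miR398, miR408, miR857), sulfate and nitrogen (miR395, miR169, miR826), auxin signalling (miR160, miR167, miR390, miR393), development (miR156, miR157, miR159, miR164, miR165, miR166, miR171, miR172, miR319, miR394, miR396), silencing machinery (miR162, miR168, miR403), and immune receptor and MYB (miR472, miR482, miR828, miR858, miR1507, miR2109, miR2118, miR5300). List families without a normalized value of 10 in any library were not analysed here. The median log2 ratio of a list with at least 3 measured families is given as its percentile among 10000 random lists of the same size, drawn from the 48 measured families and matched in 4 bins of mean expression, which describes these libraries. In a list of 3 measured families the median is the value of 1 family. The text names every list family with a value of at least 10 in 1 library, per comparison the 6 sequences with the largest ratio up and the 6 down among those with a value of at least 100 in 1 of the libraries, the 10 most abundant families by mean share, and at most 6 sequences of at least 100 with LP ratios of 2-fold or more in opposite directions. A list of 5 tRNA-like families (miR894, miR5072, miR6300, miR6478, miR8175), whose sequences resemble parts of tRNAs, was added after the data were seen.

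Among these, the other settings were scaling to the table total, edgeR 4.0.16 TMM factors, DESeq2 1.42.0 median-of-ratios size factors, no filter, a minimum of 100, a pseudocount of 10, rows as deposited, and the most abundant sequence of a family in place of the sum. The count tools served only for scaling factors in R 4.3.3, on the estimated counts, and each alternative scaling was brought to the mean total of the normalized columns so that the filter and the pseudocount keep their meaning. Added after seeing the data were scaling to the table total without the tRNA-like families, and thinning of the deeper library to the table total of the shallower one. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

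The counting of changed sequences was tested on simulated data, with reads drawn for the 215 sequences from the real levels and totals. Of these, 40 with a mean normalized value of at least 10 in the libraries compared were changed 4-fold, in 100 simulations per comparison. Of the changed sequences, 97.35% were recovered for LP against CK in roots, 99.5% in shoots, 99.35% for root against shoot under CK and 97.2% under LP. Counting error alone put 7.59, 0.910, 1.52 and 8.88 unchanged sequences per simulation past 2-fold in the same order, and 0 to 0.01 at a value of at least 100. For the changed sequences, the intervals held the true ratio in 96.2%, 96.0%, 95.45% and 96.2% of cases. The simulated reads had counting error only, which is what the intervals assume, so this checks the computation and not the real spread.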

Results

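Small RNAs of Betula luminifera, a birch tree, were profiled by sequencing in plants of 1 clone grown in sand with phosphate (CK, 1.25 mM KH2PO4) or with no KH2PO4 in the medium (LP, phosphate deficiency). The study's title asks how shoots and roots each respond to phosphate deficiency after transcription. Each of the 4 groups, root CK, root LP, shoot CK and shoot LP, has 1 library, and the shoot libraries hold pooled RNA of stems and leaves. No difference reported here therefore has a replicate check or a p-value, and the 95% counting intervals given in parentheses after a fold cover counting error of the reads only. The table lists 215 distinct mature miRNA sequences, 156 with the name of a known miRNA and 59 predicted ones, whose names start with blu. The raw reads of these sequences, each counted once, sum to 308667 in root CK, 101816 in root LP, 1015833 in shoot CK and 723599 in shoot LP, so the root LP library had the least precision. Above 0 reads were 180 sequences in root CK, 150 in root LP, 190 in shoot CK and 185 in shoot LP. Levels are the authors' normalized values, log2 ratios were taken after adding 1, and folds are plain ratios of the normalized values. A sequence was counted as higher or lower when it differed at least 2-fold with a value of at least 10 in 1 of the libraries compared.

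A few families made up most of the reads. Over the 4 libraries, miR482 averaged 21.4% of the reads, miR166 20.1%, miR156 13.5%, miR396 7.77% and miR159 5.995%, followed by miR6300, miR167, miR162, miR171 and miR160 with 2.43% to 0.805%. The 10 most abundant sequences took 81.3% of the reads in root CK, 82.5% in root LP, 86.4% in shoot CK and 89.7% in shoot LP. One predicted sequence, blu-miR7-3p, chosen after its values were seen, held 12.4% of the reads in root CK, 16.8% in root LP, 15.4% in shoot CK and 16.9% in shoot LP. Known names covered 85.4% of reads in root CK, 81.4% in root LP, 83.5% in shoot CK and 82.1% in shoot LP. A 5' U, the start of most plant miRNAs, was carried by 86.2% of reads in root CK, 88.3% in root LP, 95.9% in shoot CK and 96.5% in shoot LP. The 26-nt sequence of miR6300 (GTCGTTGTAGTATAGTGGTAAGTATT), which resembles the end of a tRNA, began with G and held 3.68%, 4.52%, 0.417% and 1.12% of the reads in the same order. Sequences with fractional raw values, as the splitting of shared reads gives, held 41.3% of the reads in root CK, 24.7% in root LP, 27.8% in shoot CK and 30.7% in shoot LP, so near-identical members of a family such as miR397a and miR397c are less certain than the family sum. Positions given below are those of the precursor on transcripts of the authors' assembly, with no genome build used here.

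The length makeup differed between tissues and with LP. Sequences of 21 nt held 79.1% of reads in root CK and 83.9% in root LP, against 67.6% in shoot CK and 56.0% in shoot LP. Sequences of 22 nt held 14.9% in root CK (exact binomial interval 14.8% to 15.05%), 7.94% in root LP (7.78% to 8.11%), 28.3% in shoot CK (28.2% to 28.4%) and 41.2% in shoot LP (41.1% to 41.3%). The miR482 family, which targets immune receptor genes, made up 92.3%, 87.1%, 94.99% and 90.9% of these 22-nt reads in that order. Sequences of 24 nt held 0.129%, 0.0982%, 0.126% and 0.211% of the reads.

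**Figure D1:**
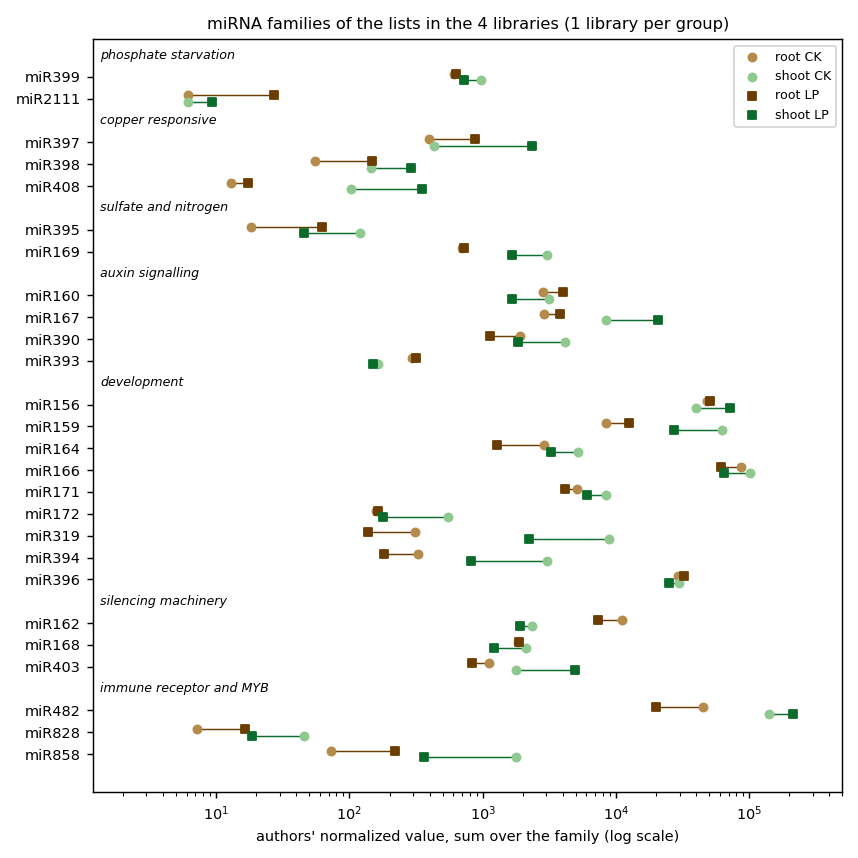
Normalized value of each list family, summed over its sequences, in the 4 libraries (log axis; circles CK, squares LP; brown root, green shoot; 1 library per group, so no error bars). Lines join CK and LP of 1 tissue: the miR397 line runs from 429.7 to 2336 in shoots, and the miR858 line from 1777 down to 361.

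In roots, LP against CK gave higher values of the copper-responsive families miR397 and miR398 and of miR395, miR2111 and miR858, and lower values of miR530, miR164, miR319 and miR482. miR397, which targets laccases, was 2.21-fold (1.90 to 2.57) higher, at 871 against 394. Its most abundant sequence miR397a alone was 1.85-fold (1.56 to 2.20) higher, under 2-fold. The call rests on the less abundant and near-identical miR397b, miR397c and miR397d. miR398, which targets copper/zinc superoxide dismutases, was 2.68-fold (1.80 to 3.97) higher. miR530, which stood in no list and is named because miR530b met the naming rule, was at 13.6 in root LP against 543 in root CK, 39.8-fold (17.0 to 123) lower. Its main sequence miR530b (TGCATTTGCACCTGCACCTCC) had 3 reads in root LP and 490.5 in root CK, a log2 ratio of -5.77. Of 143 sequences past the filter, 34 were at least 2-fold higher and 26 at least 2-fold lower under LP, and the counting interval excluded equality for 23 and 24 of them. The median log2 ratio was 0.07.

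By list, the phosphate-starvation families split in roots. miR399, which targets a ubiquitin-conjugating enzyme that limits phosphate uptake, stood at 629 under LP and 610.3 under CK, a log2 ratio of 0.04 that TMM scaling turned to -0.01. Its 19-nt form miR399c (TGCCAAAGGAGAATTGCCC; transcript TRINITY_DN28842_c1_g1, positions 635 to 722, minus strand) was 4.60-fold (2.77 to 7.61) higher, whereas the 21-nt miR399b, chosen after its values were seen, had a log2 ratio of -0.26. miR2111, which moves between shoot and root and targets an F-box gene, was 4.45-fold (1.47 to 14.9) higher, from 6 reads under CK and 10 under LP. Its members went opposite ways, miR2111a with 2 reads under CK and 10 under LP and miR2111b with 4 and 0. Of the 3 copper-responsive families measured, 2 were higher, and the list's median log2 ratio of 1.14 lay at percentile 90.8 of 10000 random lists matched on expression. miR408, which targets copper proteins, had a ratio of 1.36-fold (0.384 to 3.48) from under 13 reads in either library, so a difference was not detectable at this depth. In the sulfate and nitrogen list, miR395, which targets ATP sulfurylase, was 3.41-fold (1.76 to 6.71) higher in the sum, with the 19-nt miR395a at 0 reads under CK and 12 under LP and the 21-nt main form miR395b at 2.26-fold (0.917 to 5.47), an interval that includes equality. miR169, which targets NF-Y transcription factors, had a log2 ratio of 0.06. That miR169 value combined the 23-nt miR169c at -1.80 with the 19-nt miR169a at 0.61.

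None of the 4 auxin-signalling families reached 2-fold in roots: miR160 and miR167, which target auxin response factors, had log2 ratios of 0.50 and 0.40, miR390, which triggers trans-acting siRNAs, -0.76, and miR393, which targets auxin receptors, 0.11 (list median 0.26, percentile 78.9). The miR393 value turned to -0.50 with its most abundant sequence miR393b alone and to -0.0938 with rows as deposited. Of 9 development families 2 were lower (median -0.31, percentile 22.9), namely miR164, which targets NAC genes, by 2.26-fold (2.05 to 2.501) and miR319, which targets TCP genes, by 2.26-fold (1.68 to 3.13), its most abundant sequence miR319a alone staying under 2-fold at -0.91. The other 7 lay within 2-fold, from miR394 at -0.84 to miR159 at 0.57, with miR166 at -0.50, miR171 at -0.31, miR172 at 0.05, miR156 at 0.07 and miR396 at 0.16. The silencing families miR162, miR168 and miR403, which target a Dicer-like enzyme and Argonautes, had log2 ratios of -0.59, 0.02 and -0.43 (median -0.43, percentile 17.8), the miR168 value turning to -0.03 under TMM. In the immune-receptor and MYB list (median 1.09, percentile 92.5), miR482 was 2.24-fold (2.19 to 2.30) lower, while miR858, which targets MYB genes, was 3.05-fold (2.19 to 4.25) higher. miR828, which also targets MYB genes, had a ratio of 2.29-fold (0.636 to 7.96) from 7 and 6 reads. With 3 families measured, the list median is the miR828 value itself, and a pseudocount of 10 took both to 0.62.

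Among single sequences with a value of at least 100, those farthest down in roots after miR530b were miR169c at -1.80, miR396a-3p at -1.61, miR477-5p at -1.55, blu-miR13-5p at -1.51 and miR166f-5p at -1.50. Farthest up were miR1511b at 5.28, miR397c at 2.28, miR399c at 2.16, miR7122b at 1.76, miR858 at 1.59 and blu-miR11-3p at 1.05. miR1511b rested on 43 reads in root LP and 2 in root CK, and shoot LP held 47 reads of it despite its 7.11 times larger table. Log2 ratios in roots tended to be lower for longer sequences, though not at each step: the median was 0.97 for 18 nt, 1.58 for 19 nt, 0.69 for 20 nt, -0.02 for 21 nt, -0.50 for 22 nt, -0.48 for 23 nt, -0.91 for 24 nt and 0.11 for the 1 sequence of 26 nt, with 6 sequences each of 18 and 19 nt, 3 of 23 nt and 9 of 24 nt. The 22-nt miR482 and the 19-nt miR399c had ratios of the same sign as their length class. Scaling to the table total shifted all root ratios by 0.18, and without the tRNA-like families by 0.21, which made the split 47 higher and 23 lower. Of the 9 list families at least 2-fold apart, miR828 among them and miR530 not, 6 stayed so under every scaling. The exceptions were miR164, miR319 and miR482. No shift exceeded 0.21, so the direction of a 2-fold ratio could not change.

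In shoots, LP against CK gave higher values of the 3 copper-responsive families, miR403 and miR167, and lower values of miR858 and of the development families miR319, miR394, miR172 and miR159. miR397 stood at 2336 under LP and 429.7 under CK, 5.44-fold (5.03 to 5.87) higher, miR408 was 3.38-fold (2.86 to 4.02) higher and miR398 2.01-fold (1.71 to 2.35) higher, and the list had a median log2 ratio of 1.75 (percentile 94.2). The miR398 value lies at the 2-fold line: scaling to the table total brought its log2 ratio to 0.89, and its most abundant sequence miR398a alone was 1.64-fold (1.37 to 1.95) higher. Also higher were miR403, which targets an Argonaute, by 2.80-fold (2.68 to 2.92) and miR167 by 2.42-fold (2.38 to 2.47). The miR167 rise was carried by the 22-nt miR167b, 3.67-fold (3.58 to 3.76) higher, while the 21-nt miR167a was 1.30-fold (1.24 to 1.36) lower. miR858 was 4.92-fold (4.46 to 5.43) lower, miR319 3.99-fold (3.84 to 4.15) lower and miR394, which targets an F-box gene of the shoot meristem, 3.68-fold (3.45 to 3.94) lower. The miR319 and miR394 sums rested mainly on the 20-nt miR319a (-1.99) and miR394a (-1.91). All 20-nt sequences together had a median log2 ratio of -1.19 in shoots. Members of miR319 ranged from 0.18 for the 24-nt miR319e to -2.67 for the 23-nt miR319a-5p. Of 140 sequences past the filter, 24 were at least 2-fold higher and 39 at least 2-fold lower, with intervals that excluded equality for 24 and 38, and the median log2 ratio was -0.23.

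Neither phosphate-starvation family reached 2-fold in shoots. miR399 had a log2 ratio of -0.42, and miR2111 a ratio of 1.51-fold (0.620 to 3.67) from 12 reads in each library. In the sulfate and nitrogen list miR395 was 2.64-fold (1.99 to 3.61) lower and miR169 had a log2 ratio of -0.86. The auxin-signalling families went both ways (median -0.53, percentile 45.1): beside the higher miR167, miR390 was 2.23-fold (2.13 to 2.34) lower, and miR160 and miR393 had log2 ratios of -0.92 and -0.15, the last turning to 0.25 under TMM and 0.02 under the median of ratios. Of 9 development families 4 were lower and none higher (median -0.66, percentile 9.19), namely miR319, miR394, miR172, which targets AP2-type genes and was 3.07-fold (2.66 to 3.56) lower, and miR159, which targets GAMYB genes and was 2.31-fold (2.28 to 2.34) lower. The others had log2 ratios of 0.84 for miR156, which targets SPL genes, -0.66 for miR164, -0.64 for miR166, -0.47 for miR171 and -0.25 for miR396, the last turning to 0.15 under TMM. miR162 and miR168 had log2 ratios of -0.30 and -0.78 (silencing list median -0.30, percentile 68.7), the miR162 value turning to 0.10 under TMM. In the immune-receptor and MYB list (median -1.24, percentile 8.56), miR828 was 2.43-fold (1.53 to 3.99) lower, a call that ended with its most abundant sequence miR828a alone (-0.77) and with a pseudocount of 10 (-0.95), and miR482 had a log2 ratio of 0.58. The median of this list is again the miR828 value. Outside the lists miR530 was 2.38-fold (1.44 to 4.13) lower, at 15.6 against 37.2, and its main sequence miR530b went from -1.12 to -0.75 under TMM and -0.96 under the median of ratios.

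The single sequences farthest down in shoots were the 19-nt miR169a (TAGCCAAGAATGACTTGCC; transcript TRINITY_DN28896_c6_g4, positions 32 to 289, plus strand), 6.65-fold (5.89 to 7.54) lower, then miR477-5p at -2.55, miR159c at -2.48, miR172a at -2.30, miR858 at -2.30 and miR319b-5p at -2.26. The table places miR159c and miR319b-5p on opposite arms of the same precursor (transcript TRINITY_DN24666_c1_g4, positions 106 to 190, plus strand). Farthest up were miR397a (TCATTGAGTGCAGCGTTGATG), 5.58-fold (5.15 to 6.06) higher, miR156i at 2.42, miR1515 at 2.38, miR167b at 1.88, miR408a (ATGCACTGCCTCTTCCCTGGC) at 1.75 and the tRNA-like miR6300 at 1.52. Log2 ratios in shoots tended to be higher for longer sequences, again not at each step, with medians of -0.78 for 18 nt, -2.35 for 19 nt, -1.19 for 20 nt, -0.31 for 21 nt, 0.38 for 22 nt, 0.34 for 23 nt, 0.89 for 24 nt and 1.52 for the 1 sequence of 26 nt, and all 18 sequences of 24 nt were above 0, while 2 sequences were of 18 nt and 4 each of 19 and 23 nt. TMM shifted every shoot ratio by 0.39 and gave 47 higher and 22 lower in place of 24 and 39, and the median of ratios shifted them by 0.16 and gave 33 and 31, so the excess of lower sequences depends on the scaling. Of the list families and the 10 most abundant families, 14 were at least 2-fold apart, the tRNA-like miR6300 included, and 9 stayed so under every scaling. The exceptions were miR159, miR390, miR395, miR398 and miR828. No shift exceeded 0.39, so the direction of a 2-fold ratio could not change.

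**Figure D2:**
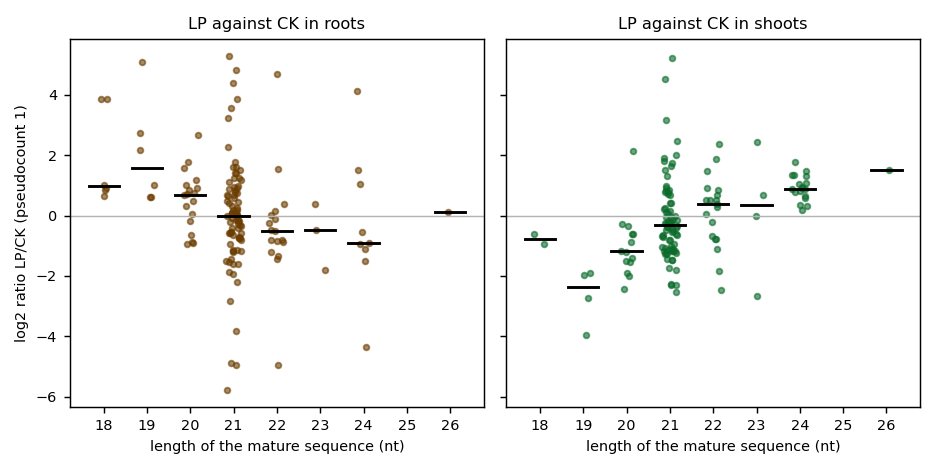
Log2 ratio LP/CK (pseudocount 1) of each sequence past the filter against the length of the mature sequence in nt, roots left and shoots right; points are sequences, black bars the medians of a length, 1 library per group. Medians at 18, 19 and 24 nt are 0.97, 1.58 and -0.91 in roots and -0.78, -2.35 and 0.89 in shoots.

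**Figure D3:**
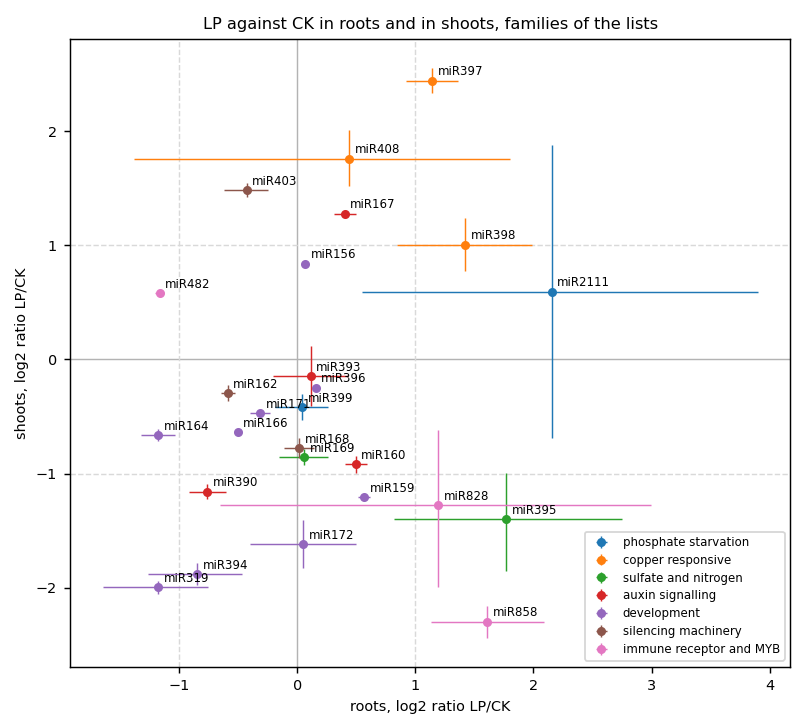
Log2 ratio LP/CK of each list family in roots (x axis) and in shoots (y axis), without a pseudocount; bars are 95% counting intervals, dashed lines mark 2-fold, 1 library per group. miR397 and miR398 lie at or beyond 2-fold higher in both tissues, and miR395 and miR858 are higher in roots and lower in shoots.

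Set side by side, the LP ratios of roots and shoots had a Pearson correlation of 0.24 across the 117 sequences past the filter in both tissues, which are not independent replicates. Of these, 8 were at least 2-fold higher in both, against 2.92 for independent lists of the same sizes, and 5 lower in both, against 6.09. The 8 were miR397b, miR397c and miR397d of 1 family, miR156f, miR398b, blu-miR11-3p, and miR1511b and miR2199. The last 2 had almost no reads under CK and similar raw reads in both LP libraries. The 8 are thus not 8 separate responses and the excess over 2.92 is uncertain. A further 7 were higher in roots and lower in shoots, against 4.77, and 2 the reverse, against 3.74. Among the sums of list families, miR397 and miR398 were at least 2-fold higher in both tissues, and miR319 was at least 2-fold lower in both. The limits given above hold for miR397 and miR319 in roots and miR398 in shoots. Outside the lists miR530 was lower in both, and miR1511 and miR2199 were higher in both through the 2 sequences with almost no reads under CK. Sequences of at least 100 with opposite ratios of 2-fold or more were miR858 (TTCGTTGTCTGTTCGACCTTG), at 1.59 in roots and -2.30 in shoots, miR7122b at 1.76 and -1.55, miR171g at 1.53 and -1.45, miR395b (CTGAAGTGTTTGGGGGAACTC) at 1.12 and -1.14, and blu-miR13-3p at -1.11 and 1.04. In roots miR171g rested on 4 and 5 reads, and its interval, like those of miR395b and blu-miR13-3p, included equality. The difference between the tissues' responses was not tested, since each rests on 1 library per treatment.

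Under CK, roots held more miR162 than shoots and less of miR319, miR858, miR394, miR408 and miR159. miR162 was 4.70-fold (4.54 to 4.86) higher in roots, whereas miR319 was 28.6-fold (25.6 to 32.2) lower, miR858 24.5-fold (19.4 to 31.4) lower, miR394 9.29-fold (8.30 to 10.4) lower, miR408 8.04-fold (4.45 to 14.9) lower and miR159 7.45-fold (7.28 to 7.62) lower. Of 142 sequences past the filter, 37 were at least 2-fold higher in roots and 53 lower, with intervals that excluded equality for all of them. Farthest up in roots were miR156b-3p (GCTTACTCTCTATCTGTCATC), 30.3-fold (22.1 to 42.7), miR160d at 4.17, miR171i-5p at 4.10, miR530b at 4.02, miR160b at 3.44 and miR482h at 3.02. Farthest down were miR171g at -6.75, from 4 reads in root CK and 1057 in shoot CK, miR172a at -5.50, from 2 and 265 reads, miR319a at -5.08, miR858 at -4.60, miR394b at -4.02 and miR159a (TTTGGATTGAAGGGAGCTCTA; transcript TRINITY_DN25641_c1_g5, positions 87 to 372, plus strand) at -3.42.

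All 3 families of the immune-receptor and MYB list were lower in root CK than in shoot CK (median -2.51, percentile 3.92), miR482 by 3.16-fold (3.13 to 3.20) and miR828 by 6.36-fold (2.96 to 16.3). Their median is the miR828 value, from 7 reads in root CK and 88 in shoot CK. Of the copper-responsive families, miR408 and miR398 were lower, miR398 by 2.63-fold (1.95 to 3.56), and miR397 had a log2 ratio of -0.13 (median -1.38, percentile 18.5). Both sulfate and nitrogen families were lower, miR395 by 6.55-fold (4.05 to 11.2) and miR169 by 4.34-fold (4.002 to 4.70). Of the auxin families, miR167 and miR390 were lower, by 2.94-fold (2.82 to 3.06) and 2.15-fold (2.05 to 2.27) (median -0.63, percentile 44.9). Of 9 development families 4 were lower and none higher (median -0.84, percentile 17.7), the fourth being miR172 by 3.49-fold (2.94 to 4.15). In the silencing list, miR162 alone reached 2-fold, with miR168 at -0.19 and miR403 at -0.65 (median -0.19, percentile 75.04), and the phosphate-starvation families had log2 ratios of -0.67 for miR399 and -0.01 for miR2111. The tRNA-like families, chosen after the values were seen, held 4.95% of the reads in root CK and 1.09% in shoot CK, with miR6300 5.30-fold (5.12 to 5.49) higher in roots. Scaling to the table total shifted every ratio by 0.73 and gave 55 higher and 37 lower, and leaving out the tRNA-like families from that total gave 56 and 37, so which tissue has more sequences at a higher level depends on the scaling. The table total also turned the ratios of miR160, miR166, miR168, miR171, miR396, miR397, miR399, miR403 and miR2111 to above 0. Of the list families and the 10 most abundant families, 15 were at least 2-fold apart, miR6300 included, and 11 stayed so under every scaling. The exceptions were miR167, miR390, miR398 and miR482. No shift exceeded 0.79, so the direction of a 2-fold ratio could not change.

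Under LP the root-to-shoot ratio lay lower than under CK for miR482, miR167 and miR403, with counting intervals that did not overlap, and higher for miR858. Against shoot LP, root LP held 10.6-fold (10.4 to 10.9) less miR482, 20.03-fold (9.75 to 58.6) less miR408, 5.91-fold (5.26 to 6.65) less miR403, 5.38-fold (5.10 to 5.68) less miR167, where miR167b was far lower and miR167a 1.17-fold (1.08 to 1.27) lower, and 16.2-fold (12.3 to 22.05) less miR319. miR162 was 3.84-fold (3.63 to 4.06) higher in roots, miR160 2.41-fold (2.26 to 2.58) higher and miR393 2.13-fold (1.67 to 2.69) higher. The miR393 value fell to 0.05 on the log2 scale with its most abundant sequence miR393b alone and to 0.70 with rows as deposited. For miR858, with a log2 ratio of -4.60 under CK, it was -0.71 under LP, and scaling to the table total turned the latter to 0.31. Of 158 sequences past the filter, 54 were at least 2-fold higher in roots and 59 lower, with intervals that excluded equality for 48 and 52. Farthest up were miR160d (TGCCTGGCTCCCTGTATGTT), 34.1-fold (20.4 to 61.2), miR160b at 4.76, miR399c at 4.60, miR169a-3p at 4.08, miR156b-3p at 3.68 and miR393a at 3.26. Farthest down were miR167b (TGAAGCTGCCAGCATGATCTGA; transcript TRINITY_DN45989_c0_g1, positions 53 to 161, plus strand), 20.2-fold (18.05 to 22.6) lower, miR408a at -4.25, miR169c at -4.11, miR482c at -4.10, miR319a at -4.00 and miR171g at -3.77.

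By list under LP, 2 of 3 copper-responsive families were lower in roots (median -1.42, percentile 7.89), with miR397 2.68-fold (2.39 to 3.02) lower and miR398 at -0.97. Of 9 development families 4 were lower (median -0.55, percentile 34.2): beside miR319, miR394 by 4.53-fold (3.56 to 5.95), miR164 by 2.55-fold (2.32 to 2.82) and miR159 by 2.18-fold (2.11 to 2.25). The auxin list held 2 higher and 1 lower family (median 0.19, percentile 71.7), the silencing list 1 higher and 1 lower (median 0.61, percentile 88.3), and the immune-receptor and MYB list 1 lower (median -0.71, percentile 27.02). miR2111 was 2.92-fold (1.13 to 7.36) higher in roots from 10 and 12 reads, miR399 had a log2 ratio of -0.21, miR395 0.45, and miR169 was 2.30-fold (2.03 to 2.63) lower. The tRNA-like families held 6.45% of the reads in root LP and 1.62% in shoot LP. Median log2 ratios by length were 4.10 at 18 nt, 4.21 at 19 nt, 1.48 at 20 nt, 0.01 at 21 nt, -1.78 at 22 nt, -2.89 at 23 nt and -3.68 at 24 nt, against 2.38, -0.93, -0.23, -0.05, -1.42, -1.45 and -0.72 in the same order under CK. Scaling to the table total shifted every ratio by 1.02 and gave 84 higher and 36 lower, while TMM shifted them by -0.33 and gave 43 and 72. The table total also turned the ratios of miR156, miR166, miR171, miR172, miR390, miR398, miR399 and miR828, like that of miR858, to above 0. Of the 14 list families at least 2-fold apart, 8 stayed so under every scaling, miR159, miR160, miR164, miR169, miR393 and miR397 being the exceptions. All kept their direction, though with shifts of at most 1.10 only ratios close to 2-fold could have lost it.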

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

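Every test in this part, of the scaling and of the length classes, was chosen after the LP ratios had been seen. For 15 of the named families and sequences, the 95% counting interval of the LP/CK ratio excluded equality in roots and in shoots, in opposite directions. These are not 15 separate results. miR159a and miR482c also count in the families miR159 and miR482, and miR169a and miR169a-3p are arms of 1 hairpin. The values that follow are the log2 ratio in roots minus that in shoots. This difference itself was not tested, because each tissue and treatment has 1 library.

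Higher under LP in roots and lower in shoots were the families miR858 (difference 3.89), miR395 (3.10), miR159 (1.77), miR160 (1.42) and miR396 (0.40). The same held for the sequences miR169a (3.34), miR7122b (3.32), miR169a-3p (2.60), miR159a (2.12) and miR393a (1.601). Lower in roots and higher in shoots were the families miR403 (-1.91) and miR482 (-1.75) and the sequences miR1515 (-3.21), miR482c (-2.27) and blu-miR13-5p (-2.09). The family values are sums, and not all members went with them. By log2 ratio in roots and in shoots, miR160a-3p (-0.565 and 0.404) and miR396b (-1.33 and 0.91) ran the reverse way. miR159a-5p (-0.63 and -1.82), miR396a-3p (-1.61 and -0.12) and miR482g (-0.81 and -0.66) were lower in both. The most abundant miR160a (0.901 and -1.16), miR159a and miR396a (0.19 and -0.26) went with their sums. miR858 rested on 71 reads in root CK and 81 in root LP, against 3440 and 463 in shoots, and miR395 on 18 and 23 against 233 and 58.5. Of the miR395 reads the 19-nt miR395a had 0 in root CK and 12 in root LP against 28 and 0 in shoots, and the 21-nt miR395b had an interval in roots that included equality, so the opposite family sums of miR395 are less certain.

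The opposite ratios were weighed against the scaling of the libraries and against the dependence of LP ratios on sequence length. Apart from miR396, 14 of 14 kept opposite signs under all 5 scalings, and the miR396 family kept them under 4 of 5. A scaling shifts every ratio of a tissue by the same amount, here at most 0.21 in roots and 0.39 in shoots, so the size of ratios already picked for being opposite fixed these counts, which decide neither for nor against scaling. The families were not tested against length, as they mix lengths. After the median ratio of the same length class was subtracted from each flagged sequence, both intervals stayed on opposite sides of equality for 3 of 9 sequences. These were miR858 (difference 3.59), miR159a (1.82) and miR482c (-1.40). The 21-nt class of miR858 and miR159a has medians of -0.02 in roots and -0.31 in shoots, too small to turn their signs. The class medians thus do not account for these 3, while the spread of ratios within a class was not weighed. The same 3 kept intervals on opposite sides when the family of the sequence was left out of the class median. The other 6 decide nothing on length. The 19-nt class has 4 sequences in shoots, and its median is the midpoint of miR169a and miR169a-3p themselves, so their values after the subtraction (difference -0.60 for miR169a; -0.37 for miR169a and 0.37 for miR169a-3p in shoots) are fixed by how the median is built, and without the family 2 sequences are left. For blu-miR13-5p (difference -0.30) both ratios then had the same sign, but the interval in roots included equality. miR1515 (-0.34 in roots and 1.99 in shoots after the subtraction), miR7122b (1.07 and -0.36) and miR393a (0.79 and -0.51) kept opposite signs, with 1 of the 2 intervals including equality. A response to LP that differs between roots and shoots stays open as an untested hypothesis, beside variation between plants and a changed share of stem, leaf or root cell types.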

How the results depend on the processing

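The 8 counts of sequences at least 2-fold higher or lower were recomputed under each alternative, and 50 recomputed counts stayed within 1.5 times the main count. Thinning the deeper library and scaling without the tRNA-like families were chosen after seeing the data. With a minimum of 100 the counts were 6 higher and 12 lower for LP against CK in roots, 9 and 19 in shoots, 21 and 33 for root against shoot under CK, and 24 and 31 under LP, as fewer sequences are then counted. Without a filter the lower counts were 60 in roots, 62 in shoots, 80 for root against shoot under CK and 91 under LP, and the higher count in shoots was 38, since low values then enter. A pseudocount of 10 gave 20 higher in roots and 15 higher in shoots, by shrinking the ratios of low values. TMM gave 47 higher and 22 lower in shoots. Scaling to the table total gave 84 higher and 36 lower for root against shoot under LP, and again 84 and 36 without the tRNA-like families, which under CK gave 56 higher. A scaling moves every ratio by the same shift, and which scaling fits was not tested. Thinning to the shallower table gave 33 higher and 29 lower in roots, 26 and 38 in shoots. It thins only the deeper library, so the counting error of the shallower one stays in both counts and its part cannot be seen. In the simulations, counting error alone put 7.59 unchanged sequences past 2-fold in roots and 0.91 in shoots. Of single ratios and list medians, 594 recomputed values left the interval around the main value and 1106 stayed in it. No ratio of 2-fold or more in a named family or sequence changed sign under a scaling, which the size of the shifts all but fixed in advance. With the most abundant sequence alone, miR169 in roots went from 0.06 to -1.80 and miR399 from 0.04 to -0.26, neither called at 2-fold in the sum. It also turned miR393 in roots from 0.11 to -0.50 and in shoots from -0.15 to 0.05, miR395 for root against shoot under LP from 0.45 to -0.59, and the medians of the sulfate and nitrogen list in roots from 0.89 to -0.34, of the phosphate-starvation list in shoots from 0.05 to -0.19, and of the auxin list in roots from 0.26 to -0.25 and for root against shoot under LP from 0.19 to -0.29, while rows as deposited turned miR393 in roots to -0.0938 and the last median to -0.01, and a pseudocount of 10 the phosphate-starvation median to -0.08. The most abundant sequence alone took 5 list family sums of 2-fold or more under 2-fold: in roots miR397 from 1.14 to 0.89 and miR319 from -1.17 to -0.91, in shoots miR398 from 1.00 to 0.71 and miR828 from -1.24 to -0.77, and for root against shoot under LP miR393 from 1.08 to 0.05, since other members of these families then drop out. A pseudocount of 10 took miR398 in shoots to 0.96, miR828 to 0.62 in roots and -0.95 in shoots, and miR2111 for root against shoot under LP from 1.45 to 0.95. Rows as deposited took miR393 for root against shoot under LP from 1.08 to 0.70. Depth limits low values most: in root LP 1 read is worth 2.73 normalized units, and the intervals of 23 of the 34 higher sequences in roots excluded equality. Libraries could not be paired by plant or block because the labels give 1 library per group and share no numbers across libraries. A comparison of LP with CK blocked by tissue was not run.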

Other observations

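The tests in this part, on length, on reads found in LP libraries and on precursor arms, were all chosen after the values had been seen. Outside the lists, some families with a value of at least 100 also stood apart under LP, chosen after their values were seen. In shoots miR477 was 3.22-fold (2.77 to 3.76) lower and miR2950 3.38-fold (2.86 to 4.002) lower, while in roots their log2 ratios were -0.06 and 0.56. The members of miR477 differed in roots: miR477-5p was 2.98-fold (1.71 to 5.65) lower, and the more abundant miR477-3p had a log2 ratio of 0.03. The miR477 family was 2.42-fold (2.22 to 2.63) higher in roots than in shoots under CK and 7.46-fold (6.30 to 8.85) under LP. The predicted blu-miR7-3p, the most abundant sequence without a known name, had log2 ratios of 0.25 in roots and 0.24 in shoots and was 2.06-fold (2.04 to 2.09) lower in roots under CK and 2.04-fold (2.01 to 2.07) lower under LP.

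The arms of the same hairpin had similar LP ratios in shoots and not in roots. In shoots the log2 ratios of the 5' and 3' arms had a Pearson correlation of 0.78 (Spearman 0.75) across 24 hairpins, above all of 10000 random re-pairings, and 20 of 24 had the same sign. In roots the correlation was 0.09 (Spearman -0.05) across 25 hairpins, at percentile 69.3 of the re-pairings, and 12 had the same sign. With a value of at least 100 for both arms it was 0.73 across 15 hairpins in shoots and -0.06 across 16 in roots. Hairpins are not independent replicates, and the difference between the tissues was not tested. Both arms can share a length, as the 19-nt miR169a and miR169a-3p do, and shoot ratios followed length. How far the correlation in shoots reflects shared length was not tested.

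LP ratios differed by length, in opposite directions in the tissues. The median log2 ratio of sequences of 22 nt or longer minus that of 20 nt or shorter was -1.36 in roots (95% bootstrap interval over sequences -1.83 to -0.80; 30 sequences each) and 1.99 in shoots (1.41 to 2.61; 42 and 20 sequences). Sequences of 1 family or hairpin are not independent, and these intervals do not cover variation between libraries. At values of at least 100 the difference was -1.14 (-1.72 to -0.31) and 1.55 (1.14 to 2.79), which argues against low counts as the whole source. Without miR482 and the tRNA-like families it was -1.33 (-1.83 to -0.70; 25 sequences each) and 2.04 (1.33 to 2.79; 36 and 16 sequences). Each sequence counts once in these medians whatever its abundance, so leaving out a few families could move them little and decides little. Size selection or RNA breakage that differed between the libraries cannot be told apart from a response to LP in either tissue, because each treatment is 1 library and a test on nested forms did not decide. Where a shorter form is contained in a longer form of the same miRNA, the longer form moved with the gradient in 9 of 9 pairs in shoots, against 6.55 expected from unrelated pairs of the same lengths, and in 6 of 8 in roots, against 5.78, so that these counts largely restate the gradient. The unrelated pairs would give 9 of 9 with a chance of 4.26%, or as many with a chance of up to 5.58% when miR319a, which stands in 2 of the pairs, is used once.

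Some sequences were listed almost exclusively in the LP libraries. With at least 5 reads in both LP libraries and at most 3 in each CK library, these were miR167b-3p, miR1510, miR1511b, miR2199, miR4415 and blu-miR21-3p, 6 sequences with 104 reads in root LP, 107 in shoot LP, 5 in root CK and 0 in shoot CK, while the rule turned round gave 3. Their normalized ratio of shoot LP to root LP was 0.294 (0.222 to 0.389), which argues against a response to LP that reaches the same level in both tissues. Their raw ratio was 1.03 (0.778 to 1.36), although the shoot LP table is 7.11 times as large. The 62 other sequences with root LP reads in the same range had a median of 2.94 and a 25th percentile of 1.30. Of those 62, 8 lay within 1.6-fold of 1. All 6 sequences here did too, but this window equals the widest of their own ratios, that of miR4415 (5 and 8 reads). Their count was thus fixed in advance and decides nothing. A candidate explanation is carry-over of a similar number of reads into both LP libraries. A response of different size in the tissues stays open, as does the source of such reads: 4 of the 6 were named after legume miRNAs, against 22 of 209 others, and 3 have a position on the authors' transcripts. The 209 others include every predicted sequence except blu-miR21-3p. Predicted sequences carry no name of a known miRNA, so the legume shares are not like for like.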
